A study of Homo sapiens with 20 samples.

How the data were processed

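ChIP-seq peak lists were compared for 20 libraries of VCaP and LNCaP, 2 human prostate cancer cell lines. The libraries targeted FOXA1, ERG, CTCF or H3K27ac, after DMSO vehicle (7 libraries) or AU-15330 (13 libraries), which the labels call a degrader of SMARCA2 and SMARCA4, at 1 µM. Each group of target, cell line, treatment and time held 1 library, so there was no replicate check of any difference, no test between conditions was made and no p-value is given between conditions. Groups and times were taken from the sample titles. The title time differed from the time in the sample characteristics in 10 of the 13 AU-15330 libraries, so the times are those of the titles and their accuracy is not known. The characteristics read 4 h and the deposited peak names 8 h for the FOXA1 and ERG libraries titled 6 h, and both read 24 h for the CTCF libraries titled 6 h. In the time course the characteristics read 4 h for the libraries titled 1 h and 2 h, and 24 h for the FOXA1 library titled 4 h.

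Per the submitters' processing notes, BWA, SAMtools and deepTools were used with the hg38 build, and no version is given there. The peak caller and its settings are not given in the sources used here. The authors deposited 10 lists of narrow peaks, 7 lists of broad peaks (H3K27ac) and 3 lists of summits (FOXA1 at 1, 2 and 4 h). The score in each deposited list was a whole-number form of the peak's significance, and the fold enrichment, a ratio, was the authors' value for each peak over the caller's own background. The deposited columns for the −log10 p-value and −log10 q-value (in the summit lists the −log10 q-value only) were also the authors' own. The smallest −log10 q-value in the deposited lists stood near a q-value of 0.05 for narrow peaks and 0.1 for broad peaks. These values were used only to rank peaks within their own list, and the strength of a peak below is its −log10 q-value. Read depths are not given in the sources used here, so the number of peaks in a list is the only measure of depth.

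Peaks on chromosomes 1 to 22 and X were used, which left out between 0.419% and 1.91% of a list. No peak lay beyond the end of a chromosome of the hg38 reference. A vehicle peak was called retained when at least 1 bp of it overlapped a peak of the matching AU-15330 list, and lost otherwise. An AU-15330 peak with no overlapping vehicle peak was called gained. Shares carry 95% Wilson intervals, which cover the counting of peaks only, and not the variation between cultures, antibodies or libraries. Peaks that overlapped the 1 kb on either side of the transcription start site (TSS) of a protein-coding transcript in GENCODE version 44 were called TSS-proximal and all others distal. The annotation held 19962 protein-coding genes on these chromosomes. Distal peaks were also weighted to the TSS-proximal peaks' deciles of strength. Moving the AU-15330 lists along the chromosomes by 20 random distances gave the overlap expected by chance, with a mean between 0.212% and 1.50% of vehicle peaks.

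Peaks within 50 kb of a TSS were counted for 10 gene lists, written before the data were examined. The lists were androgen response, luminal transcription factors, ERG-associated, housekeeping, SWI/SNF subunits, CTCF and cohesin, cell cycle, neuroendocrine, basal epithelium, and stromal, immune and endothelial. Lists shared some genes, such as SPDEF in both of the lists named at the start, and ERG in the luminal and ERG-associated lists. Each list's retention was placed among 10000 random lists of protein-coding genes matched on the number of vehicle peaks, as a description of these libraries. Retention expected from the strength of the list's peaks was given beside it. Genes were named by a rule written before the data were examined. The rule took up to 10 genes of the androgen and luminal lists with at least 3 vehicle peaks within 50 kb and the most such peaks. For ERG and CTCF the rule also took in the ERG-associated or the CTCF and cohesin list. It then took the 5 genes with the most lost peaks, the 5 with the most gained peaks, and the 3 with the most peaks all retained, each peak being given to its nearest TSS within 50 kb. It also took the strongest FOXA1 or ERG peak within 50 kb of fixed genes, of which KLK3, TMPRSS2, FKBP5 and MYC are reported. Genes the rule took that are not used here are left out of the text. Consensus sequences for forkhead, ETS, CTCF and AP-1 sites were searched on both strands within 100 bp of the peak centre and in windows of the same width 2 kb to either side.

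Many peaks lay in sequence with several copies in the genome, which the sources used here do not say was filtered. After this was seen in the data, a filter on unique sequence was added. It sampled 31-mers every 20 bp within 100 bp of each peak centre and kept a peak when at least 50% of them occurred once in hg38 without alternate loci. Both lists of a comparison were filtered. Motif windows around the summit and the weighted difference with a 2.5 kb TSS window were also added after the data were seen. The alternatives written before the data were examined were a vehicle peak covered to at least 50%, lists of equal size, the strongest 50% of either list, a 2.5 kb TSS window, weighting by strength, H3K27ac peaks joined within 5 kb instead of 12 kb, the 1000 instead of the 500 largest clusters, and a gene window of 100 kb. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. The steps were tested on simulated data made from each of the 7 vehicle lists, with 60% of TSS-proximal and 30% of distal peaks kept and 1000 peaks added. All 1000 added peaks were found as gained in each simulated list, and the retained shares matched those set. The added peaks were chosen to miss every vehicle peak and kept peaks were moved by less than their width. This recovery therefore follows from the construction and checks the code only. A loss of depth was not simulated. With a uniform loss, 2 of 69 gene list values fell outside the central 95% of 1000 random lists.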

Results

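The series profiled chromatin in prostate cancer cells after AU-15330, a degrader of SMARCA2 and SMARCA4, the ATPases of the SWI/SNF chromatin remodelling complexes. FOXA1 (a forkhead pioneer factor of luminal prostate cells), ERG (the ETS factor expressed from a TMPRSS2 fusion in VCaP), CTCF (an insulator protein) and H3K27ac (a mark of active promoters and enhancers) were mapped. There were 7 vehicle and AU-15330 pairs and, in VCaP, 6 further AU-15330 libraries at 1, 2 and 4 h. Vehicle lists held 24367 FOXA1, 7958 ERG, 42147 CTCF and 24216 H3K27ac peaks in VCaP, and 73285 FOXA1, 51571 CTCF and 33768 H3K27ac peaks in LNCaP. The matching AU-15330 lists held 12689, 7433, 35159 and 20907 peaks in VCaP and 12548, 50456 and 22183 in LNCaP. Each group had 1 library, so no difference below has a replicate check, and intervals in brackets are 95% Wilson intervals over peaks. Peak strengths and folds are the authors' own values and rank peaks within a list only. Part of each list lay in sequence that is not unique in the genome, at 23.9% of vehicle and 43.6% of AU-15330 FOXA1 peaks in VCaP, 13.3% and 48.6% in LNCaP, and 50.7% and 55.1% of ERG peaks. Vehicle peaks in such sequence were often called again (64.4%, 47.9% and 70.1% of them), so values restricted to unique sequence, a filter chosen after seeing the data, stand beside the shares of the full lists in the main comparisons. Counts around named genes are over all peaks, with the number in unique sequence given where it was at most 50% of them. The largest losses, gains and fully retained sets are of peaks given to their nearest TSS, and these lists end at a fixed number of genes, so genes with equal counts can be left out. Other gene counts are of peaks within 50 kb.

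The question for FOXA1 was whether its sites stayed occupied once the SWI/SNF ATPases were degraded. In VCaP at 6 h, 7972 of 24367 vehicle FOXA1 peaks were retained (32.7%, 32.1 to 33.3) and 16395 were lost, while 4732 peaks (37.3% of the AU-15330 list) were gained. In unique sequence 22.4% (21.83 to 23.03) were retained. Sites near TSSs were held more often than distal sites, at 44.1% (40.6 to 47.8) against 32.4% (31.8 to 33.0), and in unique sequence at 43.7% against 21.6%. With a TSS window of 2.5 kb instead of 1 kb, the difference over all peaks moved from -11.8 to -4.58 percentage points. The number of TSS-proximal FOXA1 peaks was 734 with vehicle and 801 with AU-15330, whereas distal peaks numbered 23633 and 11888.

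FOXA1 peaks around androgen response and luminal transcription factor genes were held more often than elsewhere in VCaP. Around the androgen response genes 27 of 45 FOXA1 peaks were retained (60.0%, 45.5 to 73.0), above 9999 of 10000 matched random lists, whose median was 31.4%. Around the luminal transcription factors 16 of 23 were retained (69.6%, 49.1 to 84.4), also above 9999 random lists. The retention expected from the strength of these peaks was 41.8% and 35.9%. All FOXA1 peaks were retained around SPDEF (5 of 5), a luminal ETS factor, around KLK2 and KLK3 (4 of 4 each, in a shared locus), the latter encoding prostate-specific antigen, and around GRHL2 (3 of 3), an epithelial transcription factor. Partial retention was seen at NDRG1 and STEAP4 (2 of 3 each), TMPRSS2 (3 of 6), KLK4 (2 of 4) and ACSL3 (1 of 3). Besides SPDEF, every peak nearest to AGR2 (3 of 3) and AGAP4 (3 of 3, none in unique sequence) was retained. The largest losses were at TP53INP1, a p53-inducible gene, with 6 of 6 peaks lost, and at ACSL5, a fatty acid ligase gene, PDE8B, PPM1H and the unnamed gene ENSG00000283952, with 5 of 5 lost at each. Gained FOXA1 peaks were most numerous at EYA3, PMVK, SOX1, TTC6 and CCDC200, with 4 at each, of which 1 of the 4 at CCDC200 lay in unique sequence. The TTC6 TSS lies inside the FOXA1 gene itself on chromosome 14, close to the FOXA1 TSS, so the nearest-TSS rule separates TTC6 and FOXA1 poorly.

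Other gene groups in VCaP had few FOXA1 peaks and stood near their random medians. Retained peaks numbered 3 of 10 for the ERG-associated list, 3 of 10 for cell cycle genes, 2 of 11 for SWI/SNF subunits and 2 of 8 for neuroendocrine genes. They numbered 1 of 3 for housekeeping, 1 of 4 for stromal, immune and endothelial, 0 of 4 for basal epithelium and 0 of 1 for CTCF and cohesin genes.

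The strongest FOXA1 peaks near KLK3, TMPRSS2, FKBP5 and MYC were retained in VCaP. They included the upstream KLK3 peak (hg38 chromosome 19, 50850743 to 50851113, 3.99 kb from the TSS) and the TMPRSS2 peak (chromosome 21, 41580311 to 41580611, 49.3 kb away). At FKBP5, a co-chaperone gene induced by androgen, it was an intronic peak (chromosome 6, 35722512 to 35722775). At MYC, a growth regulator gene, the peak was intergenic (chromosome 8, 127763463 to 127763948).

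Retained and lost FOXA1 peaks of VCaP carried the forkhead consensus about equally often in unique sequence, and retained sites were more often shared with other factors. The consensus lay within 100 bp of the centre in 27.2% (25.9 to 28.6) of retained, 26.1% of lost and 18.9% of gained peaks, against 3.21%, 3.10% and 3.05% in the flanks. In the full lists the retained share was 16.1% and the lost share 24.9%. FOXA1 peaks that overlapped a vehicle ERG peak were retained at 71.0% against 22.4% of those that did not, and in unique sequence at 42.3% against 19.95%. For overlap with CTCF the shares were 78.2% and 24.4%, and in unique sequence 52.5% and 20.1%. For overlap with H3K27ac they were 61.0% and 23.8%, and in unique sequence 41.3% and 18.3%. Weighted by strength in unique sequence, the shares were 33.2% against 21.0% for ERG, 50.1% against 20.3% for CTCF and 36.2% against 19.4% for H3K27ac. FOXA1 peaks with a CTCF consensus were few (56 in unique sequence), and 67.9% of them were retained against 22.3% of the others.

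LNCaP lost more of a longer FOXA1 list. At 6 h, 10324 of 73285 vehicle peaks were retained (14.1%, 13.8 to 14.3), and 2166 peaks (17.3% of the AU-15330 list) were gained. In unique sequence 8.81% (8.59 to 9.03) were retained, 5595 of 63521. TSS-proximal peaks were retained at 21.9% (20.5 to 23.3) and distal peaks at 13.7% (13.4 to 14.0), and in unique sequence at 21.3% and 8.10%. The 2.5 kb window moved the difference over all peaks from -8.16 to -3.63 percentage points. With lists of equal size, the retained share was 32.4%.

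The androgen and luminal genes of LNCaP lost most of their FOXA1 peaks, and over all peaks only the luminal list stood above the 95th percentile of matched genes, within 50 kb but not within 100 kb. The luminal transcription factors kept 14 of 46 peaks (30.4%, 19.1 to 44.8; random median 13.0%, percentile 98.8) and the androgen response genes 21 of 106 (19.8%, 13.3 to 28.4; random median 13.3%, percentile 93.4). The strength of these peaks alone gave 16.9% and 17.0%. Within 100 kb the luminal list kept 22.8% (percentile 77.2) and the androgen list 16.3% (random median 14.7%, percentile 66.6), and in unique sequence within 50 kb the androgen list stood at percentile 99.4. GRHL2 kept 4 of 8 peaks, SLC45A3 2 of 11, ELL2 2 of 7, NDRG1 2 of 6 and SORD 1 of 7 (2 of the 7 in unique sequence). ZBTB16 (0 of 8), TMPRSS2 (0 of 7), HPGD (0 of 6) and PLPP1 (0 of 6) kept none. The strongest peak at KLK3 (chromosome 19, 50850677 to 50851168) was retained. Those at TMPRSS2 (chromosome 21, 41520493 to 41520943, in an intron), FKBP5 and MYC were lost. CD34, EDEM3, ELOVL5 (a fatty acid elongase gene), MAP10 and PCOLCE2 each lost 10 of 10 nearest peaks. PSMD14 (5 of 5), CNBD1 (4 of 4) and CLPB (3 of 3) kept all of theirs. TTC6 again gained the most peaks, with 4, followed by PPP1R2 and TMEM106A with 3 and ADAMTS1 and GBA3 with 2, although 1 of the 3 at PPP1R2 and 0 of the 3 at TMEM106A lay in unique sequence.

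No FOXA1 peak was retained in LNCaP around the ERG-associated genes (0 of 32, upper bound 10.7%, percentile 0.975), the neuroendocrine genes (0 of 20, upper bound 16.1%), the basal epithelium genes (0 of 19, upper bound 16.8%) or the stromal, immune and endothelial genes (0 of 18, upper bound 17.6%). Within 100 kb these lists kept 3 of 59 (percentile 3.555), 1 of 40 (percentile 3.43), 2 of 32 (percentile 23.5) and 4 of 42 (percentile 40.9), so the last 2 were not low there. With peak lists of equal size they stood at percentiles 8.84, 18.1, 24.2 and 24.0, in the same order. Housekeeping genes kept 4 of 28, SWI/SNF subunit genes 5 of 51, cell cycle genes 3 of 27 and CTCF and cohesin genes 2 of 15, near their random medians. Retained LNCaP peaks in unique sequence held the forkhead consensus in 30.6% (29.4 to 31.8), lost peaks in 25.4% and gained peaks in 19.7%, against 3.32%, 3.21% and 2.78% in the flanks. In the full lists the order was the reverse, at 19.4% of retained and 25.3% of lost peaks.

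FOXA1 sites shared by both lines tended to share their fate. Of 17706 VCaP vehicle peaks that overlapped an LNCaP vehicle peak, 10084 were lost in both lines, against 8183 expected from each line's loss per decile of strength if losses were independent. Peaks retained in both numbered 3860 against 1959 expected. In unique sequence, 9417 of 14124 shared sites were lost in both (8598 expected) and 1650 were retained in both (831 expected). Of the sites retained in both, 10.8% were TSS-proximal, against 2.92% of those lost in both. The pairs had separate vehicle lists.

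ERG in VCaP was lost from distal sites and found at more TSSs. At 6 h, 4294 of 7958 vehicle ERG peaks were retained (54.0%, 52.9 to 55.1) and 3138 were gained (42.2% of the AU-15330 list). Over all peaks, 81.0% (78.5 to 83.2) of TSS-proximal and 49.8% (48.7 to 51.0) of distal peaks were retained. TSS-proximal peaks numbered 1051 with vehicle and 1913 with AU-15330, and distal ones 6907 and 5520. In unique sequence 36.6% (35.1 to 38.1) were retained, at 81.0% (78.5 to 83.3) of TSS-proximal but 20.8% (19.4 to 22.3) of distal peaks. TSS-proximal ERG peaks in unique sequence numbered 1025 with vehicle and 1881 with AU-15330, and distal ones 2895 and 1460. Of 1911 gained peaks in unique sequence, 1054 (55.2%) were TSS-proximal, and 83.3% of these lay in a vehicle H3K27ac peak.

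The ETS consensus, the sequence that ERG binds, marked the TSS-proximal sites. It lay in 53.7% (50.3 to 57.1) of retained, 39.9% (37.0 to 42.9) of gained and 37.9% (31.4 to 44.9) of lost TSS-proximal ERG peaks, against 3.86%, 4.22% and 4.36% in the flanks. Among distal peaks it lay in 20.4% of retained, 25.7% of lost and 12.5% of gained peaks. At TSS-proximal sites with no ERG peak, compared after these values were seen, it lay in 6.28% (4.22 to 9.25) of gained FOXA1 peaks, 4.89% of CTCF peaks and 10.6% of annotated TSSs within a vehicle H3K27ac peak. Lost ERG peaks held the forkhead consensus (11.4% against 4.95% of retained peaks) more often. Most lost peaks were distal (2292 of 2487), however, and most retained peaks TSS-proximal (830 of 1433). Of ERG peaks with the forkhead consensus 7.04% were TSS-proximal, against 28.1% of the others. The forkhead shares were not split by place, so loss and place cannot be told apart here.

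**Figure D1:**
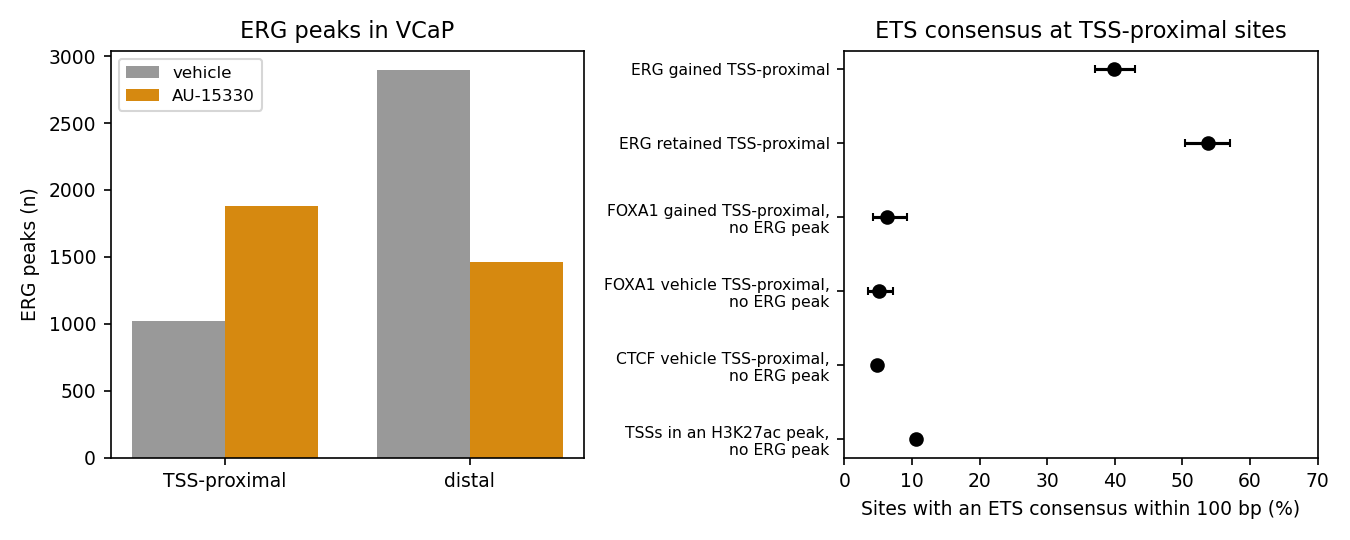
Left, number of VCaP ERG peaks in unique sequence by place, with vehicle (grey) and AU-15330 (orange), 1 library each. Right, percent of TSS-proximal sites with an ETS consensus within 100 bp, with 95% Wilson intervals; gained ERG peaks stand at 39.9% and gained FOXA1 peaks without ERG at 6.28%.

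ERG was lost from DUSP6, a MAP kinase phosphatase gene (4 of 4 nearest peaks), and from FASN (fatty acid synthase), FFAR2, NEK6 and OR11G2 (3 of 3 each). SEC14L1 kept 3 of 3 peaks, as did FAM246A and FRG2, whose peaks all lay outside unique sequence. CCDC200 gained 6 ERG peaks, 1 of them in unique sequence, and ADARB1, COBLL1, EAPP and FAM110B gained 3 each, with 1 of the 3 at EAPP in unique sequence. NDRG1, an androgen-induced gene, was the only gene of the androgen, luminal and ERG-associated lists with at least 3 ERG peaks and kept 2 of 3. The strongest ERG peak was lost at KLK3 (chromosome 19, 50842179 to 50842439) and retained at TMPRSS2 (chromosome 21, 41560331 to 41560669), FKBP5 (chromosome 6, 35722439 to 35722824) and MYC (chromosome 8, 127763449 to 127763777). Around the androgen response genes 11 of 17 ERG peaks were retained (64.7%, random median 57.9%). The luminal list kept 3 of 4, the ERG-associated list 1 of 3, cell cycle genes 5 of 6, SWI/SNF subunit genes 2 of 2, neuroendocrine genes 1 of 2 and housekeeping genes 1 of 1. Basal epithelium (0 of 2) and stromal, immune and endothelial genes (0 of 1) kept none, and the CTCF and cohesin genes had no ERG peak.

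CTCF, mapped for comparison, kept most of its sites. In VCaP, 31570 of 42147 peaks were retained (74.9%, 74.5 to 75.3) and 10.2% of the AU-15330 list was gained. In LNCaP, 43513 of 51571 were retained (84.4%, 84.1 to 84.7) and 13.7% gained. Of the strongest 50% of vehicle peaks, 98.4% were retained in VCaP and 99.6% in LNCaP. TSS-proximal CTCF peaks were retained at a share close to that of distal ones, at 72.2% against 75.3% in VCaP and 80.1% against 84.9% in LNCaP. The CTCF consensus lay in 18.8% of retained and 6.29% of lost peaks in unique sequence in VCaP, and in 16.4% and 3.41% in LNCaP.

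CTCF peaks near prostate lineage genes were lost more often than near matched genes in LNCaP, and less clearly so in VCaP. Peak strength gave part of this difference. Around the androgen response genes 25 of 39 CTCF peaks were retained in VCaP (64.1%, random median 78.0%, percentile 2.13) and 26 of 38 in LNCaP (68.4%, random median 87.5%, percentile 0.26). The luminal transcription factors kept 24 of 37 (64.9%, percentile 3.75) and 22 of 31 (71.0%, percentile 1.72). The strength of the peaks alone gave 70.0% and 82.2% for the androgen list and 71.8% and 80.4% for the luminal list. Each observed share lay below this value, furthest for the androgen list in LNCaP. The lists hold few peaks, and the difference from the strength value was not tested. In VCaP the percentiles rose to 19.3 and 14.6 with lists of equal size and to 28.45 and 8.695 with peaks within 100 kb, and in LNCaP all 4 stayed below 2. SPDEF, a gene of both lists, lost the most in both lines, with 2 of 7 and 1 of 5 peaks kept. Its losses enter both list values, and the lists were not counted without it. FKBP5 and HOXB13 kept 2 of 4 in VCaP, and the FOXA1 gene kept 3 of 4 in VCaP and 2 of 4 in LNCaP. In both lines MYC kept 4 of 5, and SMC3, a cohesin subunit gene, kept 4 of 4 in VCaP and 5 of 5 in LNCaP. The CTCF gene kept 4 of 4 and 4 of 5, RAD21 4 of 5 and 3 of 5, and SLC45A3 4 of 5 and 6 of 7. KLK4 kept 3 of 4 in VCaP, and in LNCaP GATA2 and ZBTB16 kept 3 of 4 and ACSL3 2 of 3. By nearest TSS, the largest losses in VCaP were 4 of 4 peaks at IQSEC2, PCDH19, PKHD1, RAB40AL and UBE2A, and SPDEF also lost 4, of 6. IQSEC2, PCDH19, RAB40AL and UBE2A lie on chromosome X, and whether losses differed by chromosome was not tested. In LNCaP NFIX lost 5 of 8 nearest peaks, CCDC200 5 of 13 (0 of its 3 in unique sequence), and CHDH, CLSTN1 and SPDEF 4 of 5. The largest fully retained sets were at SCGB1C2 (7 of 7, 1 in unique sequence), TTC34 (7 of 7, 3 in unique sequence) and CLPB (6 of 6) in VCaP, and at IZUMO2 (9 of 9, 3 in unique sequence), CRNN (7 of 7) and NXPH3 (7 of 7) in LNCaP. Gained CTCF peaks were most numerous in VCaP at ZNF717, FRG2C and ZNG1F (3 each, with 3, 1 and 0 of them in unique sequence), ANKRD20A1 and DNAJC2 (2 each, with 0 of the 2 at ANKRD20A1 in unique sequence). In LNCaP they were most numerous at ZNF717 (4, with 2 in unique sequence) and at TMEM248, WDR45B, EPHX3 and GOLGA6L6 (3 each, with 0 of the 3 at GOLGA6L6 in unique sequence), and ITGA2 and PTMA also gained 3.

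The remaining gene groups showed no such loss of CTCF in both lines. CTCF and cohesin genes kept 19 of 21 peaks in VCaP and 19 of 25 in LNCaP, ERG-associated genes 14 of 19 and 15 of 16, housekeeping genes 32 of 40 and 35 of 39, and SWI/SNF subunit genes 37 of 48 and 45 of 57. Cell cycle genes kept 30 of 39 and 35 of 45, basal epithelium genes 12 of 18 and 21 of 24, and stromal, immune and endothelial genes 14 of 17 and 16 of 17. Neuroendocrine genes kept 20 of 27 in VCaP and 24 of 24 in LNCaP (percentile 98.5).

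In unique sequence, CTCF peaks without the CTCF consensus were retained less often at FOXA1 sites than elsewhere. Distal CTCF peaks in unique sequence without the CTCF consensus were retained at 47.1% (44.22 to 50.01) in VCaP and 64.7% (63.2 to 66.1) in LNCaP where they overlapped a vehicle FOXA1 peak, and at 72.7% and 85.6% where they did not. The strength of those at FOXA1 sites alone gave 59.3% and 79.4%. With the consensus, the shares at FOXA1 sites were 92.8% and 97.05%. The split by consensus was not made in the full lists. There, distal CTCF peaks at FOXA1 sites were retained at 77.2% against 75.1% elsewhere in VCaP, and at 78.7% against 86.6% in LNCaP. Weighted by strength the full-list shares were 84.6% against 72.9% in VCaP and 84.3% against 84.4% in LNCaP.

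H3K27ac was held at promoters and lost from distal sites in both lines at 24 h. In VCaP 14256 of 24216 peaks were retained (58.9%, 58.2 to 59.5), at 89.1% (88.5 to 89.7) of TSS-proximal but 36.8% (36.0 to 37.6) of distal peaks. In LNCaP 15842 of 33768 were retained (46.9%, 46.4 to 47.4), at 83.0% (82.2 to 83.7) and 32.8% (32.2 to 33.3). In unique sequence distal retention was 24.8% (23.9 to 25.6) and 18.4% (17.84 to 18.99). Weighted to the strength of the TSS-proximal peaks, distal retention in the full lists was 55.8% and 48.1%. Gained peaks made up 32.0% and 28.5% of the AU-15330 lists.

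**Figure D2:**
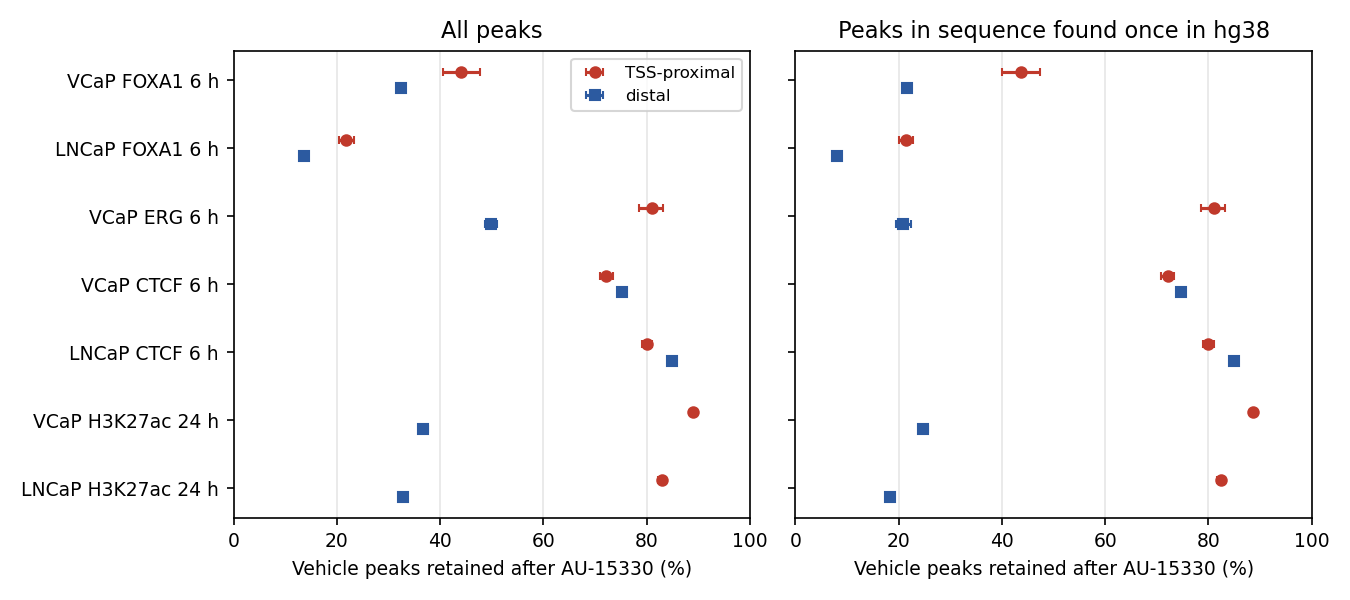
Percent of vehicle peaks retained after AU-15330 for TSS-proximal (red circles) and distal (blue squares) peaks of the 7 pairs, over all peaks (left) and peaks in unique sequence (right), with 95% Wilson intervals over peaks and 1 library per condition. Distal H3K27ac stands at 24.8% in VCaP and 18.4% in LNCaP in unique sequence, and distal CTCF at 74.7% and 84.9%.

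Prostate lineage genes lost H3K27ac more often than genes matched on peak number, but not beyond what the strength of their peaks gave. Around the androgen response genes 38 of 62 peaks were retained in VCaP (61.3%, 48.8 to 72.4; random median 79.2%, percentile 0.1) and 30 of 77 in LNCaP (39.0%, 28.8 to 50.1; random median 64.4%, below all 10000 random lists). The luminal transcription factors kept 16 of 34 in VCaP (47.1%, random median 76.5%) and 15 of 35 in LNCaP (42.9%, random median 62.9%, percentile 1.64). Peaks of these lists were weak, and their strength alone gave 52.7% and 42.2% for the androgen list and 48.5% and 36.6% for the luminal list, each within the interval of the observed share. TMPRSS2 kept 7 of 10 peaks in VCaP and 4 of 8 in LNCaP, KLK3 6 of 8 and 2 of 7, KLK2 6 of 8 and 1 of 7, and KLK4 4 of 4 and 1 of 5. FKBP5 kept 2 of 4 and 2 of 6, and HOXB13, a prostate homeobox gene, 3 of 4 and 5 of 7. In VCaP SPDEF kept 4 of 7, PMEPA1 2 of 6, NDRG1 4 of 5 and XBP1 2 of 4. In LNCaP SLC45A3 kept 3 of 7, ZBTB16 3 of 6, GRHL2 2 of 6 and ABCC4 1 of 6.

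Beyond these lists, the largest H3K27ac losses in VCaP were 6 peaks each at ABHD2 and the unnamed ENSG00000258989, and 5 each at SLC28A1, IDH2 and RAP1GAP. ABHD2, SLC28A1 and IDH2 all lie on chromosome 15, and whether losses differed by chromosome was not tested. In LNCaP MYO5C and SMCO4 lost 7 each, and COBL, MUC20 and SLC25A37 lost 6 each, with 3 of the 6 at MUC20 in unique sequence. Every nearest peak was retained at CHKA (7 of 7), a choline kinase gene, BAHCC1 and BAIAP2 (5 of 5 each) in VCaP, and at TMEM106A (5 of 5, 1 in unique sequence) and GULP1 (4 of 4) in LNCaP. Gained peaks were most numerous at BIRC3, an inhibitor of apoptosis gene, CEMIP, CNBD1, SLC35F3 and ABT1 in VCaP (3 each). In LNCaP they were most numerous at FOXD4L6, RGMB and FAM117B (4 each) and COLGALT2 and LONRF1 (3 each), with 0 of the 4 at FOXD4L6 in unique sequence. Housekeeping genes kept 27 of 32 H3K27ac peaks in VCaP and 30 of 44 in LNCaP, SWI/SNF subunit genes 33 of 40 and 27 of 48, and CTCF and cohesin genes 10 of 11 and 10 of 14. Cell cycle genes kept 25 of 34 and 22 of 38, neuroendocrine genes 11 of 18 (percentile 4.67) and 13 of 17, ERG-associated genes 9 of 15 and 4 of 14 (percentile 1.285), and stromal, immune and endothelial genes 1 of 3 and 3 of 7. With peak lists of equal size the neuroendocrine list in VCaP stood at percentile 6.635 and the ERG-associated list in LNCaP at 6.405. Basal epithelium genes kept 6 of 7 in VCaP and 1 of 11 in LNCaP (9.09%, random median 58.3%, percentile 0.04).

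At distal sites, H3K27ac retention was higher at CTCF sites, while a difference at FOXA1 sites did not hold once weighted by strength in unique sequence. In unique sequence, distal H3K27ac peaks with a FOXA1 peak were retained at 26.5% against 24.1% without in VCaP, and at 20.1% against 16.4% in LNCaP. Weighted by strength the order turned, to 24.3% against 25.1% and 18.4% against 19.5%. The full lists gave 53.3% against 27.3% and 40.6% against 21.7%, and weighted 42.7% against 33.4% and 34.1% against 30.9%. With an ERG peak in VCaP the unique-sequence shares were 36.7% against 23.3%, weighted 27.6% against 24.6%, and in the full lists 73.2% against 26.7%. With a CTCF peak they were 50.1% against 20.9% in VCaP and 37.8% against 15.2% in LNCaP, weighted 40.1% against 22.3% and 30.6% against 15.99%, and in the full lists 74.7% against 25.3% and 70.3% against 19.7%.

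Large H3K27ac clusters, made by joining distal peaks within 12 kb, kept a larger share of their length than small ones. In unique sequence the 500 largest clusters of VCaP covered 1352 kb with vehicle, of which 28.1% stayed covered, against 19.1% of 7435 kb in the others. In LNCaP 23.5% of 1746 kb stayed covered against 12.6% of 13099 kb. The largest clusters held a median of 2 peaks and the others 1 in both lines. Peak strength was not weighted here, so cluster size and strength cannot be told apart. In the full lists the shares were 51.7% against 25.2% and 59.4% against 18.3%. The 10 largest full-list clusters of each line lay mostly next to centromeres, and the place of the others was not counted. The clusters named next are those made from peaks in unique sequence. The VCaP cluster upstream of TMPRSS2 (chromosome 21, 41559881 to 41602389) kept 50.5% of its covered length. Clusters nearest to PMEPA1, NDRG1 and ZBTB16 kept 23.01%, 47.7% and 18.3%. In LNCaP the 3 largest clusters in unique sequence were nearest to CDK19 (22.2% kept), CNST (33.1%) and ERRFI1 (17.8%), and those near PPP1CB and DNAH8 kept 0%. These clusters were named after their values were seen.

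In each of the 7 pairs the strongest decile of peaks was retained more often than the weakest, with different slopes. In unique sequence, the weakest and strongest deciles were retained at 9.77% and 55.7% for FOXA1 in VCaP and at 1.64% and 37.2% in LNCaP. For ERG the shares were 17.9% and 62.8%. For CTCF they were 11.9% and 99.7% in VCaP and 25.0% and 99.7% in LNCaP. For H3K27ac they were 12.5% and 96.6% in VCaP and 6.56% and 90.3% in LNCaP.

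**Figure D3:**
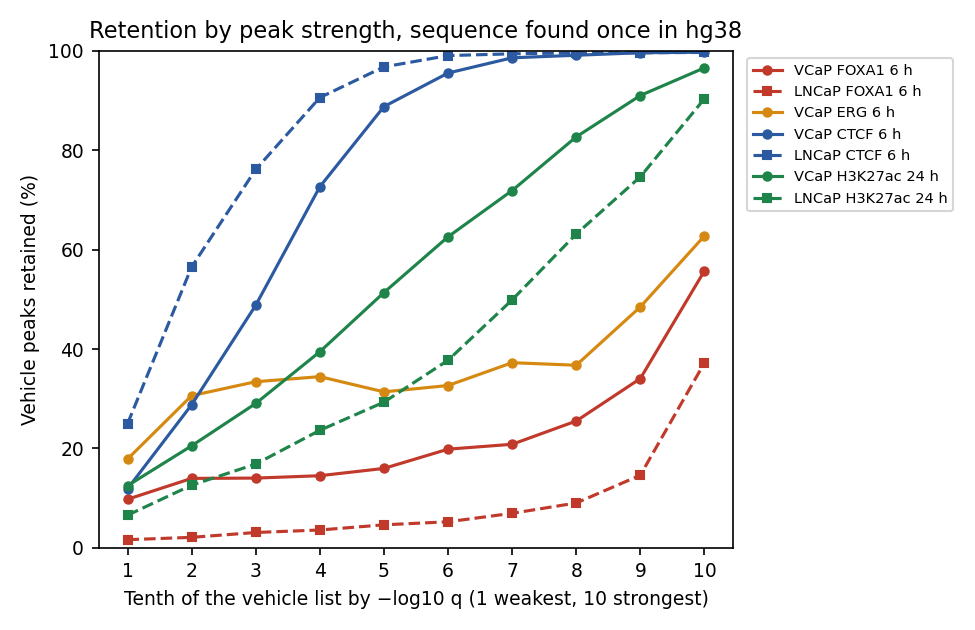
Percent of vehicle peaks in unique sequence retained after AU-15330, by decile of the vehicle list's −log10 q-value, for the 7 pairs (solid lines VCaP, dashed lines LNCaP, 1 library per condition). The strongest CTCF decile stands at 99.7% in both lines and the strongest FOXA1 decile at 55.7% and 37.2%.

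The VCaP time course asked how early these sites changed, and FOXA1 lists were already short in the library titled 1 h. The sample characteristics read 4 h for the libraries titled 1 h and 2 h and 24 h for the FOXA1 library titled 4 h, so the order of times is itself in doubt. The titles of these FOXA1 libraries carry the antibody mark TFS and the peak names of the vehicle list CSTNterm, so antibody and treatment cannot be told apart against it. Summit lists held 13332, 10440 and 10591 FOXA1 sites at 1, 2 and 4 h, and 36.6% (36.0 to 37.2), 28.1% (27.5 to 28.7) and 23.9% (23.3 to 24.4) of the 6 h vehicle peaks held a summit. Retention of TSS-proximal vehicle peaks was 51.8%, 45.5% and 49.3%, and that of distal peaks 36.1%, 27.6% and 23.1%. The summits of the 6 h AU-15330 list, counted the same way, lay in 31.7% of vehicle peaks, and in 42.6% of TSS-proximal and 31.4% of distal ones. In unique sequence the shares were 31.8%, 22.4% and 21.2% at 1, 2 and 4 h and 21.6% at 6 h, so the order of the 2, 4 and 6 h lists depended on the filter. TSS-proximal FOXA1 summits numbered 1020, 1043 and 1785. They made up 7.65%, 9.99% and 16.9% of the lists, against 5.92% of the summits of the 6 h AU-15330 list. Of the 1 h sites, 48.6% lay within 200 bp of a 4 h site, at 71.5% of TSS-proximal and 46.7% of distal sites. Against the 6 h AU-15330 list the order turned, at 47.6% of TSS-proximal and 50.2% of distal 1 h sites. For the 4 h sites it was 31.9% and 58.3%, and between the other lists the order went either way.

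H3K27ac was partly gone from distal VCaP sites from the 1 h library on, while promoters held it. TSS-proximal vehicle peaks were retained at 89.1%, 92.7% and 95.7% at 1, 2 and 4 h and 89.1% at 24 h, and distal peaks at 35.9%, 38.2%, 39.2% and 36.8%. Distal H3K27ac peaks covered 11042 kb with vehicle and 6015, 6653, 7132 and 7294 kb at 1, 2, 4 and 24 h. TSS-proximal peaks covered 10989 kb with vehicle and 9767, 11608, 14114 and 10857 kb. Of the 1 h peaks, 98.5% of the TSS-proximal and 54.2% of the distal ones were called again at 4 h. No vehicle library of the time course was used here and all times share the vehicle list of another set, so batch and treatment cannot be told apart against it, and part of the likeness between times may come from the shared control.

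**Figure D4:**
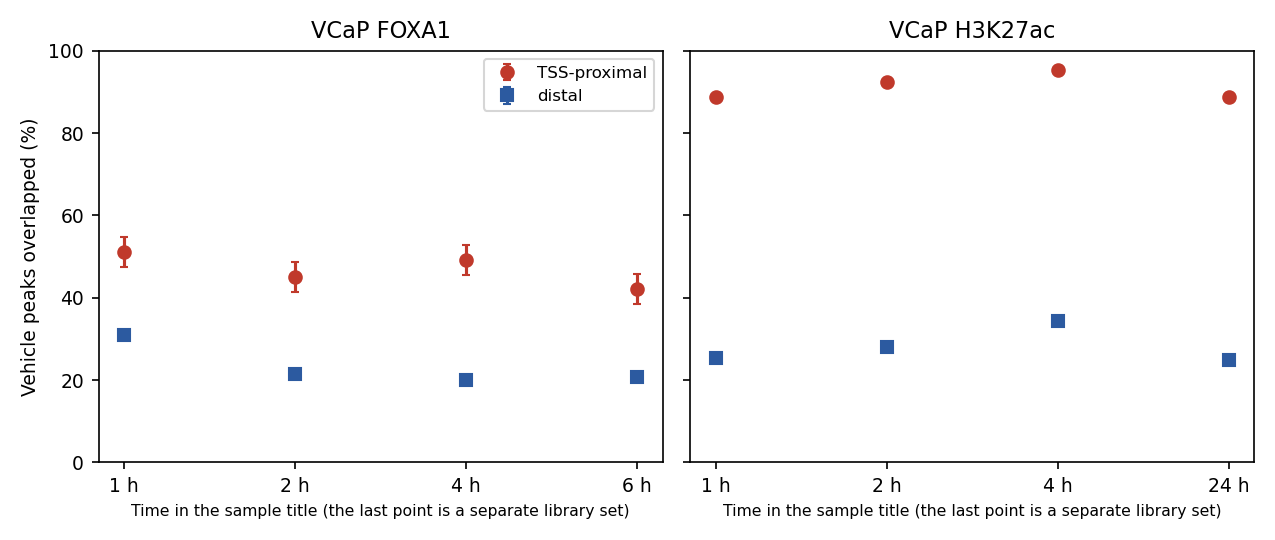
Percent of VCaP vehicle peaks in unique sequence overlapped at each time, for TSS-proximal (red circles) and distal (blue squares) peaks of FOXA1 (left) and H3K27ac (right), with 95% Wilson intervals and 1 library per time. The last time in each panel comes from the pair with its own vehicle; distal FOXA1 stands at 21.5% at 2 h and 20.8% at 6 h.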

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

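The tests on peaks in unique sequence and those weighted with a TSS window of 2.5 kb were chosen only after the result was seen; the other tests in this part were written down before.

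The number of TSS-proximal FOXA1 peaks moved in opposite directions in VCaP and LNCaP, a difference between groups. In VCaP it was 9.13% higher with AU-15330 (734 and 801 peaks), and in LNCaP it fell by 75.9% (3482 and 840 peaks). Each line had 1 library per condition, the vehicle lists differed in length and the antibody marks in the peak names differed between libraries. The difference between the lines was not tested.

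A larger share of some AU-15330 lists lay outside chromosomes 1 to 22 and X, on sequence left out of the report. The share was 1.38% against 0.854% with vehicle for FOXA1 in VCaP, and 1.18% against 0.558% for FOXA1 in LNCaP. For H3K27ac it was 0.665% against 0.464% in VCaP and 0.725% against 0.436% in LNCaP. These were 4 of 7 pairs, each above the vehicle list's Wilson interval, and the difference was not tested further.

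FOXA1 lists were shorter at 6 h in both lines, which could come from lower sensitivity of the treated library at every site, or from loss at distal sites. Lower sensitivity alone predicted a gap between distal and TSS-proximal retention, weighted by strength, within 5 percentage points, and a gap beyond 10 was set to exclude it. Over all peaks the gap was -12.9 (-16.6 to -9.31) in VCaP and -9.83 (-11.2 to -8.43) in LNCaP, which leaves both open. With a TSS window of 2.5 kb it was -5.44 (-7.97 to -2.92) and -4.79 (-5.79 to -3.78), the latter within the 5 predicted by lower sensitivity. In unique sequence it was -23.0 (-26.7 to -19.3) and -14.9 (-16.3 to -13.5), which excludes equal loss at every site as the only cause under that prediction. With the 2.5 kb window in unique sequence, -15.6 (-18.2 to -13.05) in VCaP still excludes it and -10.1 (-11.1 to -9.10) in LNCaP leaves it open. A sensitivity that fell more at distal than at TSS-proximal sites would give such a gap too, so the gap cannot exclude that. A second explanation was that retained peaks were background of open chromatin. It predicted forkhead consensus shares at most 5 percentage points above the flanks. The shares were 13.4 points above in VCaP and 16.6 in LNCaP, so retained peaks as a whole held the consensus more often than the flanks. The flanks were not matched for open chromatin, and over all peaks lost peaks held the consensus more often than retained ones. The part of the retained peaks that was background is therefore not known.

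The VCaP CTCF list was shorter after AU-15330, which could reflect weak peaks near the calling threshold or loss at strong sites. Of the strongest 50% of vehicle peaks 98.4% (98.2 to 98.6) were retained, which is what loss of weak peaks predicts. A biological effect on weak CTCF sites is not excluded by this.

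The VCaP FOXA1 list at 1 h already missed most vehicle peaks, which could come from lower sensitivity of that library or from early loss. The gap weighted by strength was -16.8 (-20.5 to -13.2), which excludes equal loss at every site as the only cause under the same prediction with the 1 kb window, while -8.32 (-10.9 to -5.72) with the 2.5 kb window leaves it open. In unique sequence the gap was -21.3 with the 1 kb window and -13.2 (-15.9 to -10.6) with the 2.5 kb window, which excludes it with either. A difference between experiments or antibodies remains possible, since no vehicle library of the time course was used here and the antibody mark of the 1 h library (TFS) is not that of the vehicle list (CSTNterm).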

How the results depend on the processing

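The filter on unique sequence, the motif windows around the summit and the weighted gap with a 2.5 kb window were chosen only after the data were seen; the other alternatives were written down before. Of 118 results with 353 alternative values, 25 were differences, the only kind that can reverse, and 0 of their 67 alternative values did. Held against its random median, a gene list's retention turned to the other side in 12 of 207 alternative values, 0 of them among the 57 of lists below the 5th or above the 95th percentile. Of these 57, however, 14 no longer lay beyond that percentile, 8 with lists of equal size, 5 within 100 kb and 1 in unique sequence. With lists of equal size, 0 instead of 4 LNCaP FOXA1 lists lay below the 5th percentile, and for H3K27ac the ERG-associated list in LNCaP moved to percentile 6.405 and the neuroendocrine list in VCaP to 6.635. Orders between values that were counted separately, or not counted, did turn in unique sequence. The forkhead share was lower in retained than in lost FOXA1 peaks over all peaks in both lines, and in unique sequence higher in LNCaP and about equal in VCaP. The FOXA1 share at 6 h, counted by summits, lay above that at 2 h over all peaks and below it in unique sequence. Retention of distal VCaP CTCF peaks with and without FOXA1 was 77.2% against 75.1% over all peaks. In unique sequence it was 51.2% against 75.6%. The distal H3K27ac difference with and without FOXA1 turned in both lines when unique sequence and weighting were joined, to 24.3% against 25.1% in VCaP and 18.4% against 19.5% in LNCaP. Of the values that answer a comparison, 44 stayed close to the main value and 102 moved. For shares and differences, staying close meant lying within the main value's interval. The number of gene lists below the random median has no interval and was held to a fixed ratio to the main number instead. All of these numbers stayed and are part of the 44, so fewer than 44 values stayed within an interval. Of the gene list values 190 stayed within the interval and 17 moved, all 17 with lists of equal size. In FOXA1, ERG and H3K27ac the gap between distal and TSS-proximal retention was below 0 in 30 of 30 values. No paired analysis was possible because each group had 1 library. Except where the construction of an alternative is named as the reason, the cause was not tested.

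Retention depended on list length by construction, since fewer peaks in a list leave fewer overlaps. The values follow in the order FOXA1 in VCaP and LNCaP, ERG in VCaP, CTCF in VCaP and LNCaP, and H3K27ac in VCaP and LNCaP. With lists of equal size they were 42.0%, 32.4%, 56.2%, 84.6%, 85.9%, 65.6% and 62.8%. With the strongest 50% of the vehicle list they were 42.5%, 20.03%, 69.5%, 98.4%, 99.6%, 84.0% and 71.9%. With the strongest 50% of the AU-15330 list they were 21.0%, 7.98%, 36.8%, 41.5%, 48.9%, 37.2% and 28.3%. With at least 50% of the vehicle peak covered, a stricter rule, they were 31.4%, 11.6%, 52.6%, 74.2%, 83.5%, 50.3% and 36.6%. In unique sequence they were 22.4%, 8.81%, 36.6%, 74.3%, 84.2% (not moved), 55.8% and 40.5%.

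The gap between distal and TSS-proximal retention moved in size. With a TSS window of 2.5 kb it was, in the same order, -4.58, -3.63, -25.7, 1.32, 3.08, -49.9 and -45.9 percentage points. Weighted by strength it was -9.83 for FOXA1 in LNCaP, -34.9 for ERG, 0.694 and 1.46 for CTCF, and -33.2 and -34.9 for H3K27ac. With lists of equal size it was -13.2 for FOXA1 in LNCaP, 0.382 for CTCF in VCaP, and -47.0 and -40.5 for H3K27ac. With 50% of the vehicle peak covered it was 6.33 for CTCF in LNCaP, and -49.0 and -43.4 for H3K27ac. In unique sequence it was -22.1 and -13.2 for FOXA1, -60.1 for ERG, and -63.9 and -64.0 for H3K27ac. For CTCF, the filter and weighting together, not counted above, gave -3.04 in VCaP and -2.49 in LNCaP, so the small gap of CTCF has no settled direction.

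Unique sequence also moved the difference between the strongest and weakest deciles, to 45.9 for FOXA1 in VCaP, 44.9 for ERG, 87.8 and 74.7 for CTCF, and 83.8 for H3K27ac in LNCaP. The percentage points of FOXA1 sites lost in both lines above the number expected fell from 10.7 to 5.80.

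In the time course, lists of equal size gave FOXA1 retention of 52.7%, 43.8% and 38.1% at 1, 2 and 4 h, and H3K27ac retention of 69.6%, 70.6% and 70.1%. In unique sequence FOXA1 gave 31.8%, 22.4% and 21.2%, and H3K27ac 56.1%, 59.3% and 63.9%. With 50% of the vehicle peak covered H3K27ac gave 47.7%, 52.2% and 55.8%. For the FOXA1 time course this alternative was not run, because summit lists have no width.

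The difference in FOXA1 retention with and without ERG, CTCF and H3K27ac in VCaP was 42.1, 47.1 and 29.3 percentage points weighted by strength, and 22.3, 32.4 and 23 in unique sequence. The difference in distal H3K27ac retention in unique sequence was 2.41 with and without FOXA1, 13.4 for ERG and 29.2 for CTCF in VCaP, and 3.67 for FOXA1 and 22.6 for CTCF in LNCaP. The extra share of length kept by the largest H3K27ac clusters was, in VCaP and LNCaP, 21.0 and 35.5 percentage points when joined within 5 kb, 19.6 and 34.2 with 1000 clusters, and 9.06 and 10.9 in unique sequence. The forkhead share of retained FOXA1 peaks was 27.2% in VCaP and 30.6% in LNCaP in unique sequence, and that of lost peaks in VCaP 26.1%. In windows around the summit, over all peaks, the LNCaP shares were 21.6% of retained and 26.7% of lost peaks.

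Read depth is not known here, so a shallower library and a loss of weak sites cannot be told apart by list length alone.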

Other observations

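The test of weaker CTCF peaks at FOXA1 sites, in both lines, and the test of ERG at TSSs were chosen only after the result was seen, the latter once the ETS share of gained ERG peaks was known.

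The CTCF consensus was more frequent among gained than lost FOXA1 peaks in unique sequence, and above retained peaks by more than its interval in VCaP only, values singled out after they were seen. It lay in 2.25% (1.78 to 2.85) of gained, 0.914% of retained and 0.125% of lost FOXA1 peaks in VCaP, and in 2.29% (1.47 to 3.56) of gained, 1.89% of retained and 0.430% of lost peaks in LNCaP.

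Gained ERG peaks at TSSs could be background of open promoters, or ERG at ETS sites of promoters. Background predicted an ETS consensus share near that of gained TSS-proximal FOXA1 peaks without ERG. The share was 33.7 percentage points higher (29.8 to 37.5). These FOXA1 peaks were chosen to lack an ERG peak, which can take promoters with ETS sites out of the comparison. The test therefore cannot exclude background of open promoters. It shows only that gained ERG peaks at TSSs held the consensus more often than these FOXA1 peaks. Another ETS factor recognised by the antibody is not excluded, and no test of it was run.

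In unique sequence, CTCF peaks without the CTCF consensus at distal FOXA1 sites were retained less often than other distal CTCF peaks. This could follow from weaker peaks. In VCaP retention was -12.2 percentage points (-15.1 to -9.32) from the value expected by strength, which leaves this open. In LNCaP it was -14.7 (-16.1 to -13.3), which excludes strength as the only cause in unique sequence under the prediction made. Over the full lists, not split by consensus, distal LNCaP shares weighted by strength were 84.3% with FOXA1 and 84.4% without. The CTCF peaks without the consensus at FOXA1 sites may be CTCF signal that depends on FOXA1-bound enhancers, and the libraries used here do not test that.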
